A study of Homo sapiens with 18 samples.

How the data were processed

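RNA of 2 kinds of tumour cell from human glioblastoma, the most malignant glial brain tumour, was measured on Affymetrix human oligonucleotide arrays of 22283 probe sets. Pseudopalisading cells form the dense rows of cells around necrotic areas of the tumour. Common tumour cells come from elsewhere in the same tumours. The labels give 18 arrays: 9 of pseudopalisading cells and 9 of common tumour cells, with 3 of each from each of 3 tumours. How cells were picked, and whether the 3 arrays of a tumour and cell type are separate captures or repeat hybridizations of one RNA, is not given in the sources used here. The tumour was therefore taken as the replicate.

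The deposited value table holds 1 signal intensity per probe set and array on a linear scale. How the authors computed and scaled these intensity values is not given in the sources used here. The mean deposited signal was 89.4 on pseudopalisading replicate 4 and lay between 207.4 and 237.5 on the other arrays. The array medians ran from 26.4 to 77.8, which is outside the 10% band set beforehand for keeping the deposited scale, so quantile normalization (limma normalizeBetweenArrays) was applied. Values were then floored at their 20th percentile, a signal of 12.56 (3.65 on the log2 scale), and log2 transformed. On this floor lay 0.195% of the values of the tested genes. Per the file headers of the experiment records, the arrays were hybridized on 4 days, here A to D, and all were of 1 chip type from 3 chip lots. Each day held as many arrays of one cell type as of the other. The chip lots, here 1 to 3, were not balanced. In tumours 1 and 2 all common arrays were of lot 1, while pseudopalisading replicates 3, 4 and 5 were of lots 3, 2 and 3. The chip lot was not used as a term. For 1 array, replicate 3 of common tumour cells, the records give a wash step other than that of the other arrays.

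Of the probe sets, 68 were controls, 19065 had 1 gene in the platform annotation, 1043 had several and 2107 had none. Probe sets with several genes or none were not named, and 31 probe sets of the sex-specific genes excluded beforehand were left out of all steps. Symbols were looked up by gene identifier in a RefSeq gene table of assembly GRCh38.p14, which matched 19053 probe sets and changed 0 symbols. The files name no genome build, so no coordinates are given. For each of 11939 genes the probe set with the highest mean over the 18 arrays was kept, and genes under the 40th percentile of mean level were left out, which left 7163 genes.

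The main test of the cell types used limma (version 3.58.1, R 4.3.3, lmFit and eBayes, two-sided) on 6 means, one per tumour and cell type, with the tumour as a block. It has 2 residual degrees of freedom and a prior of 4.854. Adjusted p values are Benjamini-Hochberg, with a threshold of 0.05. Beside it stands the fit of 18 arrays with the tumour as a block and 14 residual degrees of freedom. That fit counts arrays of one tumour as replicates, so its p values measure mostly the spread between arrays, which can be technical. Changes within each tumour and the F test of whether they differ between tumours were fitted on 18 arrays in 6 groups. A change is the log2 value in pseudopalisading cells minus that in common tumour cells, given as mean ± SD over the 3 tumours.

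Before the data were examined, 28 gene lists, the tests and the alternatives were fixed, except those named below as added or chosen later. Tests of explanations for patterns in the results were written after those patterns were seen. Their bounds were set before these tests were run, except in the test of equal loss of macrophages and microglia. Some of them judge markers whose list results were already part of the main tests. Of the 589 genes of the lists 531 were on the arrays and 413 were tested, and 22 genes stood in more than 1 list. Lists were tested with limma camera on the 6 means at its preset correlation of 0.01, and beside it with an estimated correlation and with fry, adjusted over the 28 lists. With an estimated correlation camera rests on the 2 residual degrees of freedom of the 6 means, so even a strong shift can miss the threshold. A change "called on 18 arrays" passed the threshold of 0.05 in that fit over all genes tested. The difference of a list between tumours was tested on its mean level per array. Named genes followed a rule fixed in advance: the 12 largest rises and 12 largest falls that passed the main test with one direction in all 3 tumours, with unfilled places taken by genes called on 18 arrays; in each list up to 3 members that passed, or otherwise the 2 largest changes; and VEGFA, CA9, ADM, SLC2A1, HK2, PLOD2, MKI67, TOP2A, GFAP and CHI3L1. CA9 had no probe set annotated to it alone and was not tested.

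The array numbers of the titles are shared by the cell types. Same-numbered arrays come from the same tumour, and the deviations from the means of tumour and cell type correlated above 0.1 in 4 of 9 pairs (from -0.002 to 0.319). The tumour was therefore the block of the main test, and the array number was tried as an alternative.

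The code was tested on simulated data of 7163 genes drawn independently from the real means and spreads, with 200 genes changed in all tumours in each of 5 draws. A further 200 genes were changed in tumour 1 only, and the hypoxia list was shifted. Only calls of genes outside all of these were counted as false. The test on 6 means called 9.4% of 2-fold and 82% of 4-fold changes, with 2.55% of its calls false. The fit of 18 arrays called 90.2% of 2-fold and 99.2% of 4-fold changes, but 44.7% of its calls were false, because the simulated change of each gene also varied from tumour to tumour. The test of the difference between tumours called 87.5% of 4-fold changes placed in 1 tumour. A list shifted by 0.5 (log2) was called in 100% of the draws, with a mean of 0.4 other lists called. Members of a simulated list were not correlated, so this says nothing of lists with correlated members.

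Alternatives were the deposited scale, other floors and filters, other rules for probe sets, other units of replication and blocks, the hybridization day as a term, and leaving out each tumour and each array. Camera takes no random block, so the lists were not run with one. RNA quality was measured by the ratio of 3′ to 5′ control probe sets of ACTB and GAPDH, compared by an exact paired permutation test over 3 tumours. Files were read with pandas 2.3.3 (Python 3.11.15), and figures were drawn with matplotlib 3.10.9.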

Results

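Expression was measured on 18 arrays, 9 of pseudopalisading cells and 9 of common tumour cells, from 3 glioblastomas with 3 arrays of each cell type per tumour. The comparison asks how cells of the rows around necrosis differ in expression from other tumour cells of the same tumour. The median deposited signal ran from 26.4 to 77.8, with 60 ± 13.1 in pseudopalisading and 61.3 ± 7.15 in common tumour cells (SD, n = 9 arrays). The number of tumours, 3, limits the precision.

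ZNF395, a hypoxia-induced transcription factor, was the gene that rose in pseudopalisading cells in the test on 6 means. Its level was 10.04 ± 0.70 on the log2 scale against 8.22 ± 0.88 in common tumour cells, a change of 1.82 ± 0.32 (n = 3 tumours, 3.53-fold, adjusted p = 0.0413). A further 11 genes fill the rule's list of large rises. They did not pass the test on 6 means but were called on 18 arrays and were higher in all 3 tumours. The largest of these changes was that of PLIN2, a lipid droplet coat protein, at 2.52 ± 0.87. The glucose transporter SLC2A3 was higher by 1.93 ± 0.75, the glycoprotein GPNMB by 1.85 ± 0.61 and adrenomedullin, ADM, a vasodilator peptide, by 1.75 ± 0.58. The carbonic anhydrase CA12 was higher by 1.73 ± 0.72, the myeloid receptor TREM1 by 1.71 ± 0.59 and IGFBP3, which binds insulin-like growth factors, by 1.70 ± 0.61. The transcription factor MAFF (1.66 ± 0.87), the glycolytic enzyme ALDOA (1.65 ± 0.73), the phosphatase DUSP4 (1.57 ± 0.53) and the glycogen branching enzyme GBE1 (1.55 ± 0.62) followed. Their adjusted p in limma on 6 means lay between 0.067 and 0.0964.

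Genes that fell in the test on 6 means numbered 6, and these included a water channel of astrocytes and a cell cycle kinase. AQP4, the astrocyte water channel, fell by 2.43 ± 0.63 on the log2 scale (5.4-fold), from 10.35 ± 1.80 in common tumour cells to 7.92 ± 2.17. The adhesion molecule OPCML changed by -2.02 ± 0.38, complement component C3 by -1.93 ± 0.37 and CDK1, the kinase that drives entry into mitosis, by -1.78 ± 0.12. SCRG1, a small secreted protein of the nervous system, changed by -1.71 ± 0.17 and the lipid transporter ABCA8 by -1.51 ± 0.06 (n = 3 tumours each). Adjusted p in limma was 0.0413 for 5 of these genes and 0.0434 for ABCA8. The places left in the list of falls went to FERMT1 (-2.42 ± 2.34), the matrix proteoglycan neurocan NCAN (-2.05 ± 1.27), the transcriptional inhibitor ID3 (-1.98 ± 1.21) and CX3CR1, the microglial fractalkine receptor (-1.96 ± 0.69). The small proteoglycan ASPN (-1.90 ± 1.13) and the GABA receptor subunit GABRB1 (-1.80 ± 0.55) completed it. These 6 did not pass on 6 means (adjusted p in limma from 0.067 to 0.205) but were called on 18 arrays. FERMT1 lay on the floor on 33.3% of arrays, of both cell types, so the size of its change is uncertain. ASPN lay on it on 11.1% and OPCML on 5.6% of arrays, all of pseudopalisading cells. Other probe sets moved less: those of CDK1 had changes of -0.05 and -0.84, and nearly equally bright ones of OPCML and FERMT1 had -1.10 and -0.87.

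**Figure D1:**
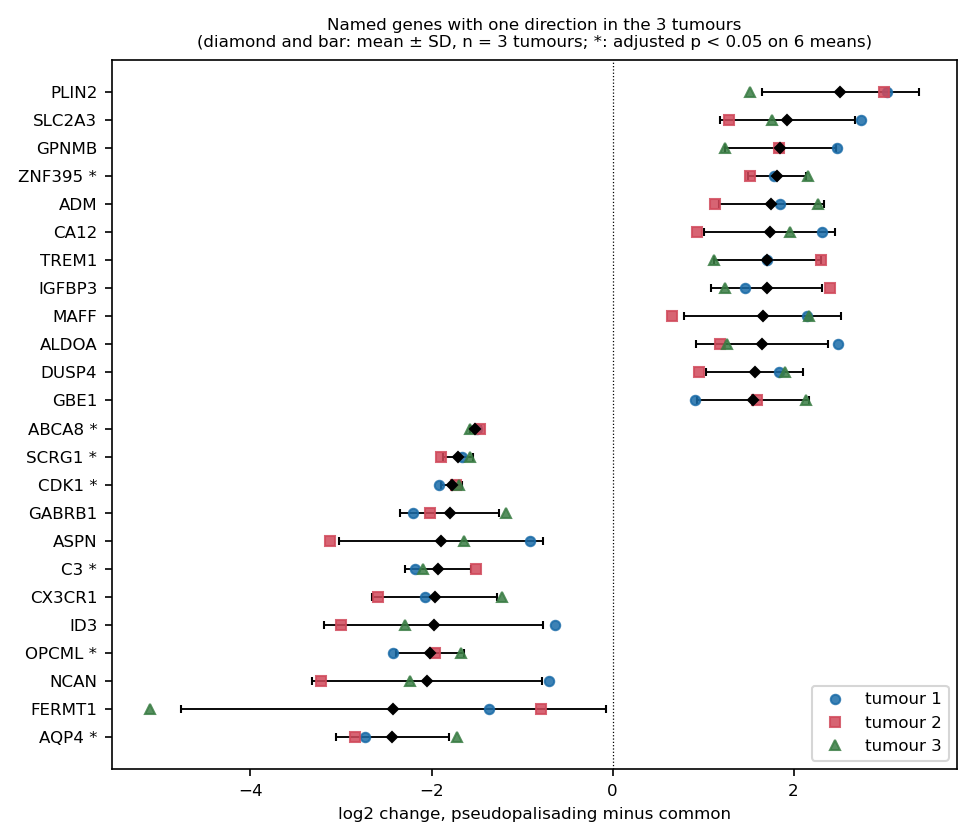
Change in log2 level of 24 genes chosen by the rule for named genes, which puts those that passed on 6 means first, pseudopalisading minus common tumour cells: coloured symbols are single tumours, diamonds with bars the mean ± SD (n = 3 tumours), and stars mark genes that passed the test on 6 means. ABCA8 and CDK1 changed by nearly the same amount in each tumour, while NCAN ran from -0.70 to -3.22. The values of FERMT1 in tumours 2 and 3 rest on arrays at the floor and are not exact.

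Over all 7163 genes, 1 rose and 6 fell on 6 means, while 1098 genes had an unadjusted p under 0.05 against 358 expected by chance. On the deposited scale 22 rose and 87 fell on 6 means, and in limma without the level filter 0 and 0 did, with 1557 genes at an unadjusted p under 0.05. On 18 arrays 357 genes were higher and 564 lower, among them all 7 genes of the first test, and 50 and 128 of these changed at least 2-fold. Of these 921 genes, 94.9% had the same direction in all 3 tumours, which their selection by the shared change favours. On the deposited scale the fit of 18 arrays called 77 genes higher and 439 lower, so that 14.9% of calls were higher against 38.8% after quantile normalization. That scale moved the median change of all genes from 0.01 to -0.11. With pseudopalisading replicate 4, the array of lowest scale, left out, the deposited scale gave 321 and 509. Leaving out tumour 2, or any one of pseudopalisading replicates 1, 2, 4, 5 and 6 and common replicate 3, left 0 calls in limma on 6 means, with 968 to 1165 genes at an unadjusted p under 0.05. Without tumour 1 the counts were 0 and 2, and without tumour 3 they were 35 and 69. Among 450 genes called on 18 arrays that had more than 1 probe set, 148 had a probe set of the opposite sign. Data were simulated with 200 genes changed in all tumours, 200 others in tumour 1 only and a list shifted, and with changes that vary between tumours. There 44.7% of the calls on 18 arrays fell outside these genes and were false. That share depends on the number of changed genes and is not an estimate for the 921 calls. With the hybridization day as a term the counts on 18 arrays were 434 and 637. Within day C, with 4 arrays per cell type from 2 tumours, they were 146 and 238. Day A, with 2 arrays per cell type from 2 tumours, gave 0 and 5 in limma (889 genes at an unadjusted p under 0.05). Day D, with 2 per cell type from 1 tumour, gave 0 and 0 (1174 genes), and day B held 1 array per cell type.

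Genes of the hypoxia response rose as a group. Of 31 tested members, 25 were higher and 0 lower on 18 arrays, and 24 were higher on 6 means when adjusted over the list alone. The median change was 0.88, with 0.91, 0.82 and 0.89 in the 3 tumours. Beside ZNF395 and ADM, the growth factor VEGFA was higher by 0.94 ± 0.45, the glucose transporter SLC2A1 by 1.25 ± 0.39, hexokinase HK2 by 0.93 ± 0.26 and the collagen-modifying enzyme PLOD2 by 0.56 ± 0.12. These 4 were called on 18 arrays but not on 6 means (adjusted p in limma 0.134, 0.067, 0.108 and 0.199). The list had adjusted p = 3.4e-19 in camera, adjusted p = 0.2 with an estimated correlation, and adjusted p = 0.044 in fry. Within single days and tumours its median lay between 0.65 and 1.19.

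Glycolysis genes rose too, with 11 of 18 members higher and 0 lower on 18 arrays, 9 higher on 6 means adjusted over the list alone, and a median of 0.64. SLC2A3 and ALDOA had the largest changes. The list had adjusted p = 4.4e-07 in camera and adjusted p = 0.47 with an estimated correlation. Within days its median lay between 0.27 and 0.98. Angiogenic factors had a median of 0.31, with ADM, CXCL8 (1.37 ± 0.90) and VEGFA higher on 18 arrays among 12 members, and 3 higher on 6 means adjusted over the list alone. Within days it lay between 0.15 and 0.76. Their camera adjusted p was 0.042, with adjusted p = 0.52 with an estimated correlation, and the call was lost without tumour 3 (median 0.101, adjusted p = 0.214). It was also lost when any one of pseudopalisading replicates 3, 5 and 6 or common replicate 4 was left out (adjusted p from 0.0509 to 0.0678), without the level filter (0.138), with the mean of probe sets (median 0.05, adjusted p = 0.134) and without the tumour term (0.109).

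Stress genes formed 2 further groups. Of 20 genes of the unfolded protein response, 7 were higher and 0 lower on 18 arrays and 5 were higher on 6 means adjusted over the list alone, with a median of 0.33 (0.11 to 0.79 within days) and adjusted p = 7.4e-06 in camera (adjusted p = 0.52 with an estimated correlation). The transcription factor DDIT3 was higher by 1.01 ± 0.98 and the pseudokinase TRIB3 by 0.94 ± 0.57. Of 8 genes of the list of metallothioneins, which bind zinc and copper, 3 were higher on 18 arrays: MT1H (0.69 ± 0.11), MT1F (0.61 ± 0.30) and MT3 (0.42 ± 0.28). The list also holds the zinc transporter SLC30A1, which had a change of -0.306 ± 0.275 and was not called. The largest change of the list, 0.74 ± 0.10 of MT1X, was not called. On 6 means 3 members were higher when adjusted over the list alone. The median was 0.46 (0.32 to 0.67 within days), with adjusted p = 0.00043 in camera and adjusted p = 0.47 with an estimated correlation, and the call was lost without the tumour term (adjusted p = 0.083). Ribosomal protein genes had 9 of 33 members higher on 18 arrays and 0 on 6 means adjusted over the list alone, with a median of 0.31 (0.02 to 0.51 within days), adjusted p = 4.2e-06 in camera and adjusted p = 0.52 with an estimated correlation. RPL18 (0.87 ± 0.62, with 0.50 on a probe set of similar brightness) and RPS3 (0.69 ± 0.03) changed most. Their medians per tumour were 0.34, 0.48 and 0.07. Without the first 2 hybridization days 4 of these 33 genes were higher.

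Of 22 genes of the mesenchymal glioblastoma class, 7 were higher and 1, the hyaluronan receptor CD44 (-0.53 ± 0.15), was lower on 18 arrays. IGFBP3, LGALS3 (1.25 ± 0.23) and CHI3L1 (1.18 ± 0.37), a secreted glycoprotein, were among the higher ones. On 6 means 6 were higher when adjusted over the list alone. The median was 0.38 (0.18 to 0.65 within days), with adjusted p = 0.00014 in camera and adjusted p = 0.47 with an estimated correlation. Of 19 genes of the proneural class, 5 were lower and 0 higher. These were CSPG5 (-1.65 ± 1.43), the oligodendroglial transcription factor OLIG2 (-1.22 ± 0.27), SOX4 (-0.82 ± 0.93), DCX (-0.82 ± 0.28) and PDGFRA (-0.59 ± 0.56). On 6 means 2 were lower when adjusted over the list alone. The list fell with a median of -0.28 (-0.48 to 0.06 within days) and adjusted p = 0.012 in camera, with adjusted p = 0.47 with an estimated correlation. The proneural call was lost without tumour 2 (median -0.091, adjusted p = 0.0819), without the level filter (0.0669) and without the tumour term (0.109). Without the first 2 hybridization days 1 member was higher and 2 were lower, and a dimmer probe set of OLIG2 went the other way by 0.21.

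Proliferation genes fell as a group. Of 28 members, 18 were lower and 0 higher on 18 arrays, and 20 were lower on 6 means adjusted over the list alone. The median was -0.65, and -0.50, -0.71 and -0.87 in the 3 tumours. TOP2A, the topoisomerase of dividing cells, was lower by -1.43 ± 0.35 (adjusted p in limma 0.067 on 6 means), beside the kinase CDK1. MKI67, which encodes the Ki-67 antigen, had a change of 0.18 ± 0.07 on its brightest probe set, whereas its 3 other probe sets had -0.34, -0.77 and -0.10. The list had adjusted p = 1.1e-14 in camera, adjusted p = 0.2 with an estimated correlation and adjusted p = 0.044 in fry. Within single days and tumours its median lay between -0.85 and -0.32.

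Astrocyte markers fell, with 10 of 17 lower and 0 higher on 18 arrays, 4 lower on 6 means adjusted over the list alone, and a median of -0.73 (-1.45 to -0.13 within days). Beside AQP4, the glial filament gene GFAP had a change of -1.47 ± 1.18. The list had adjusted p = 4.9e-07 in camera and adjusted p = 0.52 with an estimated correlation. Over the 3 tumours, 9 neuron markers had a median of -0.27 and 9 oligodendrocyte markers one of -0.24, and neither list passed (camera adjusted p = 0.43 and 0.22). In tumour 3 the medians were -0.27 for astrocyte, -0.22 for neuron and -0.40 for oligodendrocyte markers. The difference between the lists was not tested. The glycolytic enzyme ENO2, listed as a neuron marker, was higher by 1.28 ± 0.70. VSNL1 had a change of -0.61 ± 0.35. The oligodendrocyte genes ASPA (-1.02 ± 0.65) and ENPP2 (-0.75 ± 0.32) were called on 18 arrays.

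Macrophage and microglia markers fell, with 6 of 14 lower and 0 higher on 18 arrays and 7 lower on 6 means adjusted over the list alone. The median was -0.52, and -0.21, -0.85 and -0.30 in the 3 tumours, and within single days and tumours it lay between -1.11 and 0.06. CX3CR1 and MS4A6A (-1.27 ± 0.84) changed most. Antigen-presenting genes of MHC class II had 5 of 9 members lower on 18 arrays, 5 on 6 means adjusted over the list alone, and a median of -0.66 (-0.95 to -0.24 within days): HLA-DPA1 (-1.36 ± 1.06), HLA-DRB1 (-0.86 ± 0.65), HLA-DRA (-0.74 ± 0.31), HLA-DMB (-0.68 ± 0.24) and HLA-DPB1 (-0.67 ± 0.17). Both lists had adjusted p = 0.00026 in camera and adjusted p = 0.52 with an estimated correlation. Interferon response genes had 4 of 25 members lower: IFI44L (-1.13 ± 1.17), IFI6 (-1.01 ± 0.95), IFI44 (-0.96 ± 0.13) and PSMB9 (-0.55 ± 0.14). On 6 means 1 was lower when adjusted over the list alone. Their median was -0.22 (-0.81 to 0.54 within days), and 0.11, -0.49 and -0.32 in the tumours, with adjusted p = 0.0067 in camera and adjusted p = 0.58 with an estimated correlation. In tumour 1 the median was 0.54 on day B, with 1 array per cell type, and -0.18 on day C, with 2. The interferon call was lost without tumour 2 (median -0.066, adjusted p = 0.284), without tumour 3 (-0.189, adjusted p = 0.0865) and on the deposited scale without pseudopalisading replicate 4 (-0.121, adjusted p = 0.0607).

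The other lists did not pass in camera with all arrays. Without tumour 1, lists of collagens and matrix (adjusted p = 0.0225), neutrophil markers (0.0132) and pericyte markers (0.0361) were called lower, as were neutrophil markers without tumour 3 (0.0277) and pericyte markers without the first 2 hybridization days (0.0182). Pericyte and smooth muscle markers had a median of -0.14 over 8 genes (RGS5, -0.87 ± 0.74), and endothelium markers one of -0.31 over 3 genes (PECAM1, -0.76 ± 0.32; ENG, -0.31 ± 0.80). Neutrophil markers had -0.41 over 4 genes (FPR1, -0.55 ± 0.40; MMP9, 0.48 ± 0.83), lymphocyte markers 0.00 over 5 (MS4A1, -0.51 ± 0.43; CD3E, 0.32 ± 0.20) and erythrocyte markers 0.28 over 2 (HBB, 0.65 ± 1.09; CA1, -0.09 ± 0.12). Collagens and matrix genes had a median of -0.11 (COL3A1, -2.53 ± 2.31; COL1A2, -1.34 ± 1.79), and extracellular proteolysis one of 0.09 (ADAMTS1, 0.71 ± 0.53; CTSL, 0.65 ± 0.45). Cell death genes stood at 0.13 (BID, -0.79 ± 0.48; BNIP3, 0.71 ± 0.59), heat shock genes at 0.01 (HSPA6, 0.95 ± 1.03; CRYAB, -0.66 ± 1.14) and immediate early genes at -0.10 (CCN2, -0.67 ± 0.76; JUND, 0.67 ± 0.23). Inflammatory chemokines and cytokines stood at 0.07 (TNFAIP3, 0.64 ± 0.77), cholesterol synthesis at -0.06 (SC5D, -0.81 ± 0.25; MSMO1, -0.41 ± 0.31) and oxidative phosphorylation at -0.06 (NDUFS1, -0.62 ± 0.34; ATP5F1C, -0.59 ± 0.40). Of 13 called lists, 0 passed with an estimated correlation on 6 means, 2 passed in fry (hypoxia and proliferation), and 4 passed with an estimated correlation on 18 arrays (hypoxia, proliferation, glycolysis and mesenchymal). The estimated correlation on 6 means was 0.01 for hypoxia and for proliferation, the preset value. Correlation between members therefore does not account for the loss of these 2 calls, and that test rests on 2 residual degrees of freedom. All 13 were called with the hybridization day as a term on 18 arrays. MT1F, MT3, SLC30A1, CD44, SOX4, DCX, PDGFRA, HLA-DRA, HLA-DMB, HLA-DPB1, IFI44 and PSMB9 stand outside the rule for named genes and were chosen after their values were seen.

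**Figure D2:**
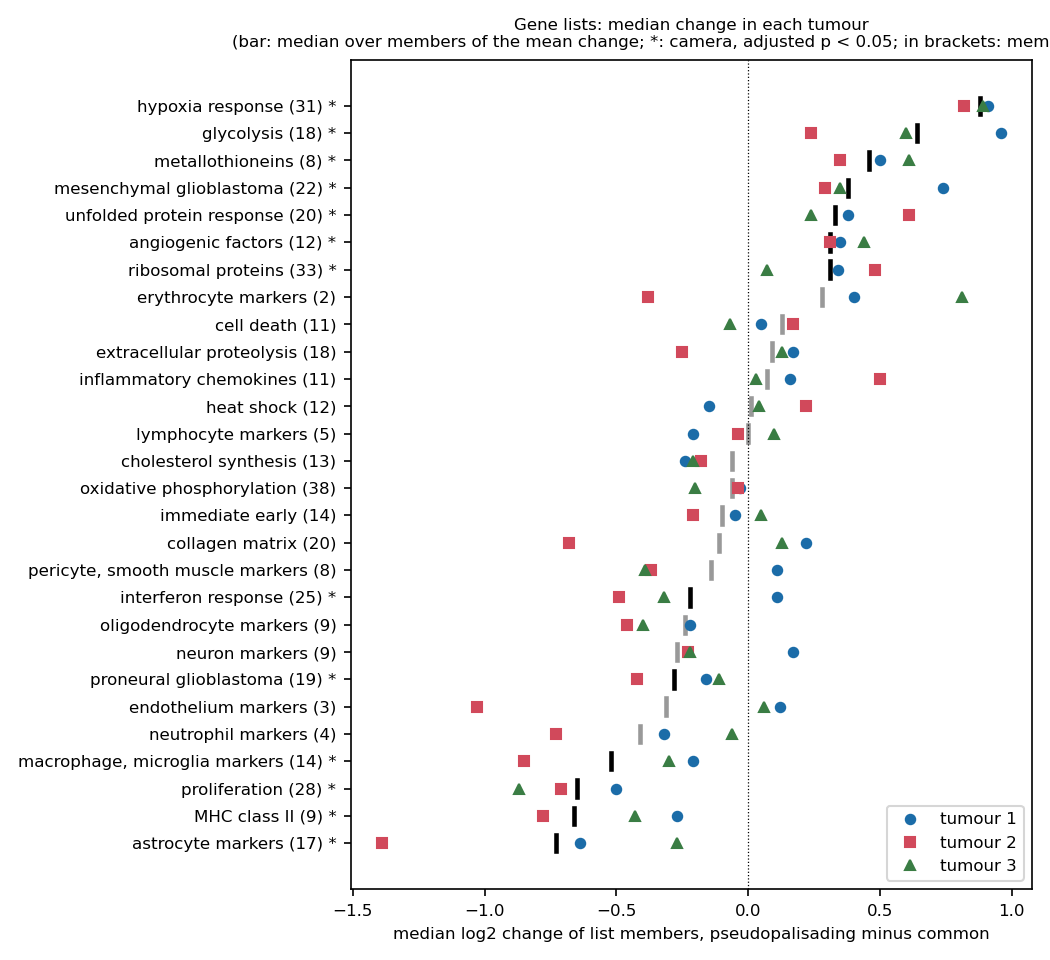
Median log2 change of the tested members of 28 gene lists, pseudopalisading minus common tumour cells, in each of 3 tumours (coloured symbols), with a bar at the median over members of the mean change, and stars for the 13 lists called by camera at its preset correlation. The hypoxia response lies between 0.82 and 0.91 in the 3 tumours, whereas astrocyte markers run from -0.27 to -1.39.

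**Figure D3:**
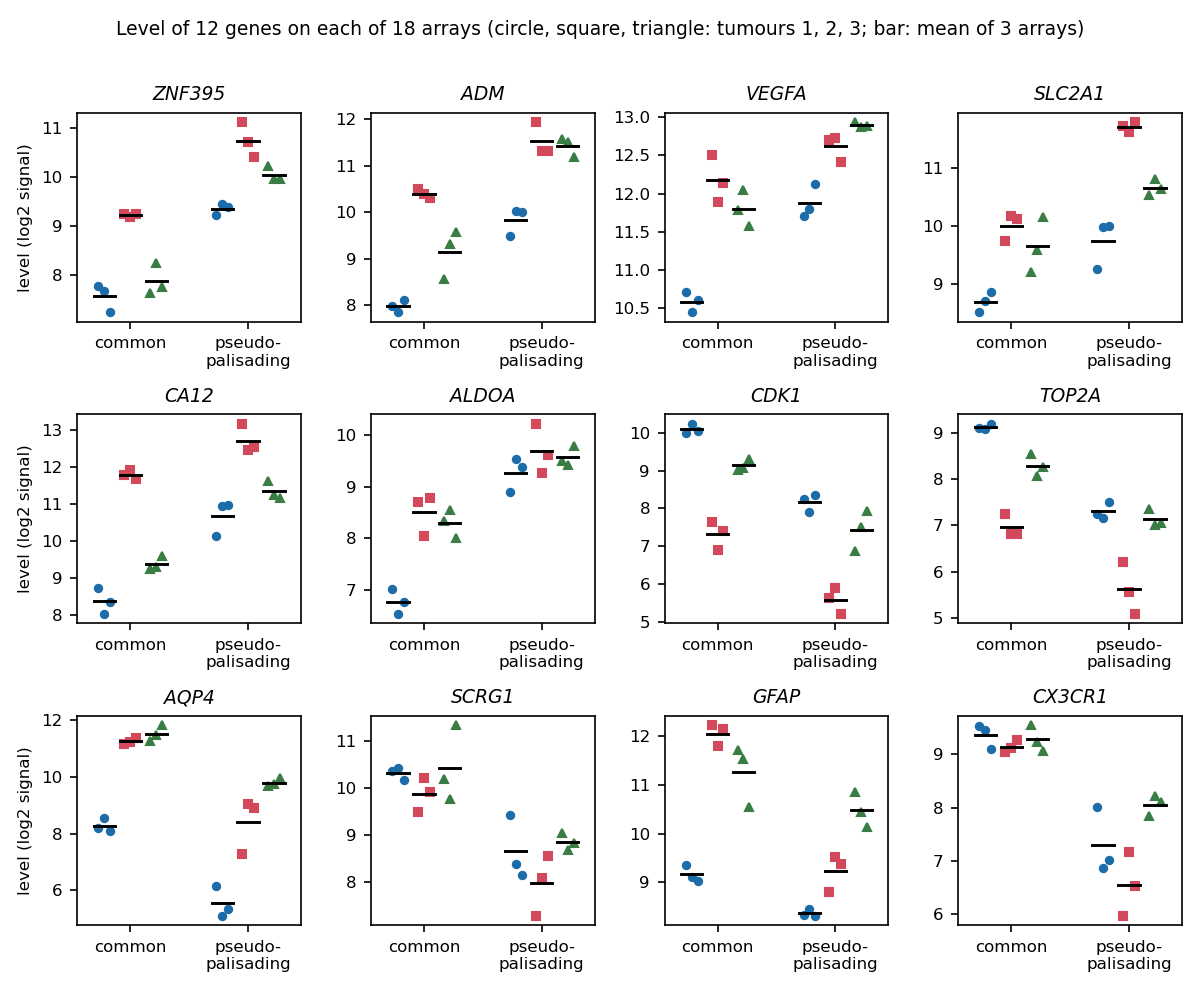
Level of 12 genes on each of 18 arrays, as normalized log2 signal, with common tumour cells to the left and pseudopalisading cells to the right. Symbols mark the 3 tumours and bars the mean of 3 arrays; for CDK1 and ZNF395 the distance between cell types is similar in each tumour although the tumours differ in level.

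Each tumour was also tested by itself, with 3 arrays per cell type and p values that measure only the spread between arrays. In tumour 1, 136 genes were higher and 190 lower. In tumour 2 the counts were 266 and 396, and in tumour 3 they were 116 and 203. In all 3 tumours 17 genes were higher and 20 lower, where independent lists would share 0.082 and 0.3. The tests of the 3 tumours share one estimate of spread per gene. Their lists are therefore not independent, and these numbers are not a chance expectation. Among the genes called higher in each tumour were ZNF395, ADM, ALDOA, CA12, CHI3L1, GPNMB, HK2, IGFBP3, LGALS3, PLIN2, SLC2A1, SLC2A3 and TREM1. Among those called lower in each were ABCA8, AQP4, CDK1, CX3CR1, GABRB1, OLIG2, SCRG1 and TOP2A. In opposite directions in 2 tumours were 14 genes. The count of tumour 1 was 159 to 191 without common replicate 1, 2 or 3 or pseudopalisading replicate 2, and that of tumour 3 was 183 to 202 without pseudopalisading replicate 7, 8 or 9 or common replicate 7 or 9.

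The change differed between tumours for 185 genes (interaction F test in limma, adjusted), and 99 of these had their largest change in tumour 2. CSPG5 had changes of -1.52, -3.15 and -0.29 in tumours 1, 2 and 3 (adjusted p of the difference in limma 0.000787), and GFAP had -0.80, -2.83 and -0.78 (0.00874). NCAN had -0.70, -3.22 and -2.24 (0.0082), and PLIN2 3.03, 3.00 and 1.52 (0.00632). As groups, astrocyte markers (medians -0.64, -1.39 and -0.27, adjusted p = 0.0013 in limma) and collagen and matrix genes (0.22, -0.68 and 0.13, adjusted p = 0.031 in limma) differed between tumours. In tumour 1 the median of collagen and matrix genes was 0.79 on day B, with 1 array per cell type, and 0.09 on day C, with 2. The number of genes whose change differed between tumours was 60 on the deposited scale, 104 with the mean of probe sets and 113 to 255 when single arrays were left out. It fell by more than 1.5 times without common replicate 1 (113), 2 (122) or 6 (116) or pseudopalisading replicate 6 (121).

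Across genes, the changes of tumours 1 and 2 correlated with r = 0.287 (rho = 0.228), those of tumours 1 and 3 with r = 0.334 (rho = 0.293) and those of tumours 2 and 3 with r = 0.372 (rho = 0.315). Genes are not independent replicates and no p was computed. Differences between tumours took 45.6% of the variance of the tested genes, cell type 12%, their interaction 9.72% and arrays within a tumour and cell type 32.7%.

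The control probe sets of ACTB and GAPDH had log2 ratios of 3′ to 5′ signal of 4.57 ± 0.478 in pseudopalisading and 4.65 ± 0.495 in common tumour cells (n = 9 arrays each). The paired difference was -0.08 ± 0.30 (n = 3 tumours, exact permutation p = 0.75, two-sided, where 0.25 is the smallest that 3 tumours allow). In single tumours it was -0.37, 0.23 and -0.11. The log2 ratio of 3′ to middle signal had a paired difference of -0.05 ± 0.47, with -0.58, 0.34 and 0.09 in single tumours. Single arrays had log2 ratios of 3′ to 5′ signal from 3.535 to 5.795, so 3′ signal was far above 5′ signal on every array.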

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

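The test of equal loss of all macrophages and microglia was chosen only after the result was seen. The largest single-array distances were searched in 210 groups of 9 arrays, where 18 far arrays were found. Independent groups of 9 independent values would give about 10.5. Arrays of one tumour are not independent and some genes are members of the lists searched, so 10.5 is not a chance expectation here. Pseudopalisading replicate 4 had a median deposited signal of 26.4 against a mean of 64.15 on the other 8 arrays of its cell type, and common replicate 5 had 77.8 against 59.26. Pseudopalisading replicate 1 had a log2 ratio of 3′ to 5′ control signal of 3.535 against 4.696.

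In what follows, highest and lowest hold among the 9 arrays of the named cell type, and the second value is the mean of the other 8. Among gene lists, pseudopalisading replicate 1 had the highest mean log2 level of pericyte markers (7.941 against 6.861) and of oxidative phosphorylation (9.286 against 8.927). Among pseudopalisading arrays it also stood highest for PECAM1 (9.797 against 7.288), MS4A6A (10.4 against 7.959) and RGS5 (8.217 against 6.661). Pseudopalisading replicate 9 was the lowest of its cell type for extracellular proteolysis (7.246 against 7.573), and pseudopalisading replicate 6 for ENG (4.078 against 6.092). Common replicate 8 was lowest for erythrocyte markers (5.235 against 6.596) and HBB (4.599 against 7.213). Common replicate 4 was lowest for lymphocyte markers (5.415 against 6.215) and CD3E (4.002 against 6.461), and highest for MSMO1 (9.188 against 7.843). Among common arrays, replicate 5 was lowest for IFI44L (6.607 against 7.287), common replicate 7 for GBE1 (9.832 against 10.88), and common replicate 9 was highest for SCRG1 (11.32 against 10.06).

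The change between the cell types differed between tumours for 7 named genes (interaction F test in limma, adjusted p): CSPG5 (0.000787), FERMT1 (0.0043, resting on arrays at the floor in tumours 2 and 3), PLIN2 (0.00632), NCAN (0.0082), GFAP (0.00874), IFI44L (0.00997) and HLA-DPA1 (0.015). It differed for the lists of astrocyte markers (0.0013) and of collagens and matrix (0.031). Of the probe sets with several genes or none, which no other comparison used, 1269 were tested apart. Of these, 133 were called on 18 arrays, 77 higher and 56 lower.

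Astrocyte markers as a list, and the genes AQP4, SCRG1 and OPCML, were lower in pseudopalisading cells, as was GABRB1 on 18 arrays. Normal brain tissue mixed into the common tumour cells would lower neuron and oligodendrocyte markers as well. Their pooled median change was -0.22 ± 0.1 (18 genes, n = 3 tumours), above the bound of -0.5 set before that test was run. In tumours 1 and 2 the pooled medians were -0.12 and -0.23, against -0.64 and -1.39 for astrocyte markers. Oligodendrocyte markers alone had -0.22 and -0.46 there, and neuron markers 0.17 and -0.23. These smaller changes argue against normal brain tissue as the whole cause in tumours 1 and 2. In tumour 2 the oligodendrocyte value lay close to the bound, so normal brain tissue as a part of the cause stays open. In tumour 3 the pooled median was -0.31 and that of astrocyte markers -0.27, so for that tumour normal brain tissue stays open. A difference in RNA quality shared by the tumours would move the 3′ to 5′ ratio one way in each, but its change was -0.08 ± 0.3 with both signs. A part played by RNA quality in single tumours is not excluded by this. A lower expression of these genes by the tumour cells around necrosis may remain, as may fewer astrocytes alone, and these 2 were not separated.

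Proliferation genes were lower in pseudopalisading cells. Dilution by macrophages or endothelium would raise their markers, but the higher of the 2 medians, that of endothelium, was -0.28 ± 0.64 (3 genes), and that of macrophages and microglia was -0.45 ± 0.34. On the deposited scale or without the percentile floor the median of the list was -0.645 or lower. Only 0.195% of the values of tested genes lay on the floor, so taking it away could hardly move the median. The deposited scale moved the median change of all genes to -0.11, toward a fall, so this check cannot decide on the scaling of dim genes. Less division of the tumour cells around necrosis may account for the pattern, as a hypothesis found on these arrays that was itself not tested.

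CX3CR1 and TLR7 were lower (TLR7 -1.65, adjusted p in limma 0.000273 on 18 arrays, chosen after its value was seen) while TREM1 and GPNMB were higher. Fewer macrophages and microglia in the pseudopalisades could account for the falls, since 100% of the 6 called markers were lower, but not for the rises. Relative to the members' median, 7 of 14 markers changed on 18 arrays, among them TYROBP (0.90) and ITGAM (0.67) above it and CX3CR1 (-1.32) and MS4A6A (-0.63) below it. This cannot decide on an equal loss of all such cells, since probe sets can differ in background and other cells may express a marker. The fit also counts arrays as replicates. A change in the kind or state of macrophages and microglia stays open, as does expression of TREM1 and GPNMB by tumour cells.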

How the results depend on the processing

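The alternatives without the first 2 hybridization days, the deposited scale without pseudopalisading replicate 4, and those applied to the counts on 18 arrays were chosen after seeing the data. The count on 6 means, 1 higher and 6 lower, moved most, and the cause was not tested except where fewer arrays or another unit of replication explain it by construction. It was 22 and 87 on the deposited scale, 19 and 28 with the floor at the 40th percentile, 20 and 31 with the stricter filter and 19 and 33 with trend and robust. It was 0 and 0 in limma without the filter, with every probe set, without the first 2 hybridization days and on the deposited scale without pseudopalisading replicate 4 (unadjusted p under 0.05 for 1557, 1487, 983 and 1094 genes).

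With arrays as replicates it was 357 and 564, 434 and 637 with the hybridization day as a term, and 255 and 438 with tumour and cell type as a random block. For the pairing, the array number as a replicate block gave 323 and 494 on 18 arrays, and 6 means without the replicate block (no tumour term) gave 0 and 0 in limma, with 352 genes at an unadjusted p under 0.05. The array number as a block changed no list's call.

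Leaving out 1 tumour or array gave 0 to 35 higher and 0 to 69 lower on 6 means, the highest without tumour 3. Counts above 1.5 times the reported ones also came without common replicate 7 (17 and 29), common replicate 8 (7 and 13), pseudopalisading replicate 8 (3 and 12), pseudopalisading replicate 9 (7 higher), and pseudopalisading replicate 7 and common replicate 9 (2 higher each). On 18 arrays it gave 216 to 398 and 350 to 611, with 216 and 350 without tumour 1, 230 higher without tumour 2 and 225 and 367 without tumour 3, and the deposited scale gave 77 higher. Within tumour 1 it gave 159 to 383 genes and within tumour 3 183 to 390. On the deposited scale these were 79 and 78, and tumour 2 had 382 without pseudopalisading replicate 4. Genes whose change differed between tumours were 60 on the deposited scale, 104 with the mean of probe sets and 113 to 255 with 1 array left out.

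Correlations between tumours 1 and 2, 1 and 3, and 2 and 3 were 0.21, 0.24 and 0.28 without the filter and 0.341, 0.401 and 0.434 with the stricter filter. With 1 array left out they were 0.225 to 0.312, 0.279 to 0.375 and 0.317 to 0.396. Without the first 2 days tumours 2 and 3 had 0.264. The shares of variance for tumour, cell type and arrays within were 37.1%, 10.5% and 42.6% on the deposited scale, 36%, 10% and 43.8% without the filter, and 50.1%, 13.6% and 27% with the stricter filter. Without the first 2 days they were 54.9%, 13.8% and 18.8%, with 12.5% for the interaction.

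Lists called were 0 higher and 0 lower in camera with an estimated correlation and 1 and 1 in fry. Of 1002 values of lists under alternatives, 958 stayed on their side of the threshold, 39 lost a call and 5 gained one. Of 1106 values of 75 named genes under settings, 787 stayed, 38 lost and 281 gained a call, and of 1565 with a tumour or array left out, 1447 stayed, 63 lost and 55 gained one. A call turned to the opposite direction in 0 of them. ZNF395 was called under 23 of 36 alternatives (adjusted p in limma from 1.07e-07 to 0.982). Lists with a random block were not run, since camera takes none. Signal over background limits dim genes: 0.195% of tested values lay on the floor.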

Other observations

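The counts of splits that part every tumour or every same-numbered pair were added to the planned ones. The genes that follow were called in each of the 3 tumours and were picked out after their values were seen. The ribonucleotide reductase subunit RRM2 was lower by -1.69 ± 0.44, cyclin B1, CCNB1, by -1.35 ± 0.30, the mitotic kinase PBK by -1.28 ± 0.23 and the spindle checkpoint gene MAD2L1 by -1.23 ± 0.19 (n = 3 tumours). The protease inhibitor SERPINA3 had a change of -1.49 ± 0.27, the potassium channel KCNJ16 one of -1.44 ± 0.42 and the endothelin receptor EDNRB one of -1.32 ± 0.34. Higher in each tumour were the MYC antagonist MXI1 (1.12 ± 0.10), the lipid droplet protein HILPDA (1.10 ± 0.26) and the kinase MKNK2 (0.95 ± 0.07). None of these passed limma on 6 means (adjusted p from 0.067 to 0.0775), where 1098 genes had an unadjusted p under 0.05. RRM2, CCNB1 and MAD2L1 are members of the proliferation list and MXI1 and HILPDA of the hypoxia list, so they were already part of those list results.

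A copy number difference between the sampled areas of a tumour would shift the genes of a chromosome together. The largest median change of an autosome relative to all genes was -0.14, for chromosome 4 in tumour 1, with adjusted p = 0.28 in camera with an estimated correlation, and a bound of 0.3 had been set beforehand. This argues against whole-chromosome differences as a source of the changes, and says nothing of shorter segments.

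Of the 10 splits of the 6 means into 3 and 3, 1, the real one, gave 7 genes and the highest other gave 0; so few splits cannot reach a share under 0.05. The 3 other splits that part every tumour gave at most 0. Of 100 splits of the 18 arrays, 1, the real one, gave 921 genes and the highest other gave 317, so a chance assignment of single arrays is excluded for that count. Chance between tumours is not, since at that level only the 10 splits exist. Of 99 other splits that part every same-numbered pair, the highest gave 286. Within tumours 1, 2 and 3 the real split gave 326, 662 and 319 genes, and the highest others 2, 6 and 1, again with 10 splits each, too few to decide. Of 100 assignments of cell types within tumours, 3, the real one included, gave as many as or more than the 185 genes whose change differed between tumours. The other 2 gave 395 and 316. They relabelled all 3 pseudopalisading arrays of 1 or 2 tumours, so the shared change itself can appear there as a difference between tumours. The next highest gave 150. The share of 3 in 100 excludes a chance assignment of single arrays only. The 3 arrays of a tumour and cell type can be repeats of one RNA, so chance differences between captures are not excluded.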
